A study of Mus musculus with 2 samples.

How the data were processed

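The data came from 2 samples of mouse intestinal epithelium profiled by RNA sequencing on an Illumina HiSeq instrument, 1 from a control mouse and 1 from a mouse deleted for Myh9. Per the labels' protocols, both C57BL/6 mice were 8 weeks old, both genotypes received tamoxifen daily on 5 days, and RNA was taken at day 5. The epithelium was released from intestinal pieces of 3 to 7 mm by 30 min in the cold with EDTA (30 mM) and dithiothreitol (1.5 mM), and RNA was extracted with TRIzol. Which exons of Myh9 were deleted is not given in the sources used here. The group of each sample was taken from its genotype label, wild type for the control and Myh9-/- for the knockout. Each column of the table was matched to its sample by the animal number that the table and the sample title share.

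HISAT2, StringTie and the mouse build mm10 are named in the submitters' processing notes, without versions or roles. The deposited table held 12631 gene rows with 1 signal value per sample, an expression level whose unit is not given in the sources used here. The design had assumed a named unit such as FPKM or TPM; the same size rule was used for the values as found. No deposited value was below 1. Of the deposited values, 1118 in the control and 1218 in the knockout had more than 6 significant digits, and after 1 was subtracted no value did. The values were therefore read as an expression level printed to 6 significant digits, to which the authors had added 1. All levels reported here have that 1 removed. The deposited fold change, a ratio computed by the authors, equalled the knockout value over the control value in every row, to within a relative difference of 1.22e-07, so it is a fold on the scale of level plus 1. Genes low in both samples had no row: the smallest sum of both levels was 0.794, and the filter that produced this is not given in the sources used here. After removal of the added 1, 129 rows were at 0 in the control and 91 at 0 in the knockout. A second deposited sheet repeated 26 of the genes with identical values.

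The depth of the libraries is unknown. The listed levels summed to 671114 in the control and 634492 in the knockout, which are sums of levels, not read totals. Among 1720 genes above 0 in both samples and under 2, at most 4 shared the same between-sample ratio to 4 digits, so no steps of whole reads were found and no counting interval could be given. The strand setting of the library and of the counting is not given in the sources used here, so overlapping and antisense genes could not be told apart. Members of families with near-identical copies (defensins, Gsdmc genes, Reg3 genes, glutathione transferases, immunoglobulin segments, Snora73a and Snora73b) can share reads, and their separate values are uncertain.

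With 1 sample per group there is no replicate error, and no test or p-value is given for any gene. Differences were described by size. The log2 fold was computed on level plus a pseudocount of 1, which understates the difference for genes at low levels. A gene was included when its larger level was at least 1, which kept 12152 rows, and it was called higher or lower at the 1.4-fold threshold that the labels state. A gene below 1 in 1 sample was thus included only through the other sample, which fixed its direction. Before the data were examined, 56 gene lists were fixed for cell types, intestinal regions, pathways and technical markers. For each of the 54 lists with at least 3 included genes, the median log2 fold was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A percentile describes these 2 libraries only, since genes are not replicates, and some genes stand in more than 1 list. A list outside the central 95% of its random lists (below percentile 2.5 or above 97.5) is called outside the random range; with 54 lists, 2.7 would fall there by chance if genes varied independently.

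The rule for named genes was also set before the data were examined. It took Myh9, the 12 genes highest and the 12 lowest by log2 fold among genes with a larger level of at least 5 and a proper gene symbol, up to 2 members per direction of each list described, and the genes that define a list by name. Myh14, Reg3g, Cd74 and Igkc were added after their values were seen, as were the genes the authors picked, and are marked as such. Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, in which 12229 of the row names were found as symbols. Spreadsheet conversion had turned 18 row names into dates; these rows entered the counts but could not be named. Some members of the lists are not reported here by name. Another 8 names stood on 2 rows each.

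The alternatives set before the data were examined were a pseudocount of 0.1 or none, no filter on low levels, a filter at 5, a 2-fold threshold, and 3 rescalings of the libraries: by the median fold, by totals without mitochondrial-genome genes and the 20 most abundant genes of either sample, and by a trimmed mean of M values (30% trim on fold, 5% on level). The procedure was tested on simulated data for the comparison of knockout with control, over 12152 genes, with 200 changed singly and another 20 changed together as a list. With noise set to the robust SD of the observed log2 folds, 0.46, the 1.4-fold rule found 86.0% of 50 genes planted at a log2 fold of 1, 88.0% of 50 at -1, and 100% of those at 2 and at -2. It also passed 29.6% of the 11932 unchanged genes. Because the noise was set from the observed folds, real differences included, this share does not measure how many observed calls noise would give. A list of 20 genes planted at a log2 fold of 0.5 came out at percentile 99.97, and 20 unchanged genes at percentile 33.6. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.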

Results

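The transcriptome of small intestinal epithelium was compared between 1 control mouse and 1 mouse in which Myh9, the gene for the heavy chain of non-muscle myosin IIA, had been deleted after tamoxifen. Non-muscle myosin IIA is the motor that contracts actin bundles at cell junctions, in the cell cortex and in the cytokinetic ring. The series is titled for epithelial homeostasis, necroptosis and colitis-associated adenoma, and the comparison asks which transcripts differ soon after the loss of the gene. RNA was taken at day 5 in both animals. Each group held 1 sample, so no value below has a replicate error, and every difference is between these 2 libraries. Levels are the deposited expression values with the added 1 removed, in a unit not given in the sources used here, and folds are on the scale of level plus 1. Sequencing depth is unknown.

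Myh9 was 99.5 in the control and 13.6 in the knockout, 6.89-fold lower, a log2 fold of -2.78. The gene lies on chromosome 15 from 77760587 to 77842175 on the minus strand of mm10 (ENSMUSG00000022443.17, protein coding). Myh14, which encodes another non-muscle myosin II heavy chain, was 194 in the control and 193 in the knockout; it was chosen after its value was seen. Of the 10 included genes of the myosin II list, which also holds light chains and regulators, 1 was higher by 1.4-fold (Rock2, 12.7 against 18.8), 1 was lower (Myh9) and 8 lay between. The library labelled knockout thus had the lower level of the targeted gene.

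Of 12152 genes with a level of at least 1 in either sample, 1936 were at least 1.4-fold higher in the knockout, 1985 were at least 1.4-fold lower, and 8231 lay between. At 2-fold, 546 were higher and 520 lower. The median log2 fold of all included genes was -0.0037, and the robust SD was 0.46. Rescaling both libraries without mitochondrial-genome genes and the 20 most abundant genes multiplied the knockout by 1.08, shifted the median log2 fold to 0.096, moved the split to 2463 higher and 1551 lower, and raised the share of higher genes among those called from 49.4% to 61.4%. The called genes were 32.3% of those included, and without replicates the share that chance alone would give is unknown.

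The largest difference upward among symbol-named genes was in Ly6d, a GPI-anchored surface protein of the Ly6 family, at 1.19 in the control and 85.0 in the knockout, a 39.2-fold difference. Ly6a, which encodes Sca-1, a marker of regenerating intestinal epithelium, was 1.34 and 77.9, 33.7-fold higher (chromosome 15, 74994877 to 74998031). Saa1, an acute-phase serum amyloid A, was 0.92 and 33.9, and Il1rn, the interleukin-1 receptor antagonist, was 0.20 and 13.1. The reductases Cbr3 (0.19 and 13.3) and Akr1b8 (8.35 and 101) and the acyltransferase Mboat1 (3.40 and 46.8) were also among the 12 highest. The other 5 were listed at 0 in the control: Gml at 12.2, Anxa10 at 10.9, Snora73b at 12.6, and the immunoglobulin segments Igkv4-80 at 19.7 and Ighv1-69 at 12.8 in the knockout. At the other end, Gsdmc4, a gasdermin C gene, was 67.0 in the control and 6.72 in the knockout, 8.80-fold lower, and its neighbour Gsdmc2 was 38.3 and 5.33. Olfm4, a marker of crypt-base stem cells, was 619 and 113, 5.45-fold lower (chromosome 14, 79984081 to 80023139). Tcea3 (51.4 and 5.64), Oat, which encodes ornithine aminotransferase (564 and 102), Adck3 (57.4 and 8.72), Slc5a4a (38.3 and 5.84) and Akr1c14 (9.04 and 0.63) were also among the 12 lowest, each with a larger fold than Olfm4. Snora73a (6.75), Ighv2-6 (6.66) and Igkv12-38 (6.13) were listed at 0 in the knockout. Snora73a and Snora73b are near-identical neighbouring copies on chromosome 4, so their opposite values are uncertain. Ly6d, Gml, Ly6a, Gsdmc4 and Gsdmc2 all lie on chromosome 15, which also holds Myh9. Ly6e, located between Gml and Ly6a, was 139 and 122. Whether position near the targeted gene plays a part was not tested.

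**Figure D1:**
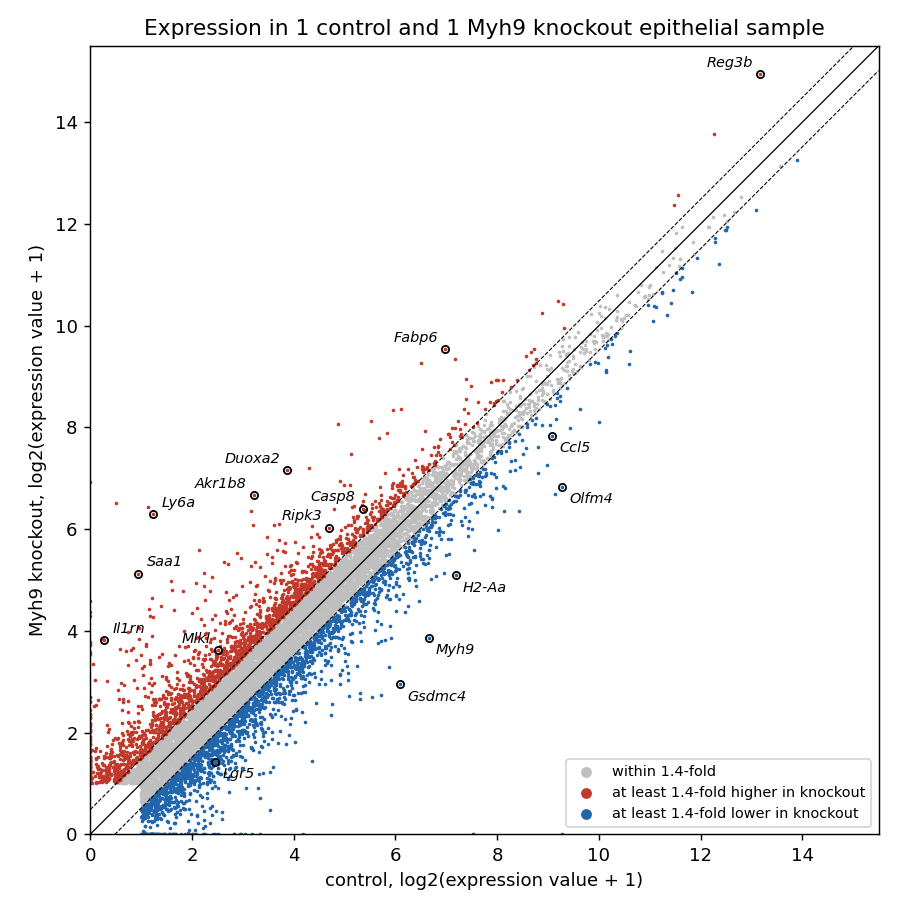
Expression level plus 1 of each included gene in the control (x axis, log2) and the Myh9 knockout (y axis, log2), 1 sample each; the solid line marks equal levels and the dashed lines 1.4-fold. Red points (1936 genes) lie above the upper dashed line and blue points (1985 genes) below the lower one; Myh9 sits at 99.5 and 13.6, far below the line.

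Of the core necroptosis genes, Ripk3 and Mlkl were higher in the knockout. Ripk3, the kinase that triggers necroptosis, was 25.0 in the control and 64.2 in the knockout, 2.51-fold higher (chromosome 14, 55784995 to 55788865). Mlkl, the membrane-disrupting effector that it phosphorylates, was 4.69 and 11.2, 2.15-fold higher (chromosome 8, 111311797 to 111338177). Casp8, a caspase that restrains necroptosis and drives extrinsic apoptosis, was 39.9 and 83.6, 2.07-fold higher. Ripk1 was 13.6 and 16.0, within 1.4-fold. Of the 19 genes of the necroptosis list, 6 were higher, none was lower and 13 lay between, with Fadd at 6.84 and 5.12 and Tnfaip3 at 11.4 and 8.05. The list's median log2 fold was 0.17, at percentile 89.4 of random lists, inside the random range.

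The p53 targets stood further from the rest. Of 16 measured, 11 were higher and none was lower, with a median log2 fold of 1.00, above all 10000 random lists. Phlda3, a p53-induced repressor of Akt, was 1.25 in the control and 9.69 in the knockout, and Plk2 was 0.66 and 5.18. The other 5 lay between. Plk2 and some other higher members were below 1 in the control and were included only through the knockout, so the filter fixed their direction. Of the 20 apoptosis genes, 6 were higher, 1 was lower and 13 lay between, with a median log2 fold of 0.25 at percentile 98.3. Bax, which permeabilizes mitochondria, was 41.3 and 102, 2.42-fold higher, and the death receptor gene Tnfrsf10b was 2.25 and 4.68, whereas the initiator caspase gene Casp9 was 7.46 and 4.76. The pyroptosis and inflammasome list went both ways, with 6 of 17 genes higher and 6 lower. Il1b was 0.16 and 1.32 and Il1rn is given above (0.20 and 13.1), while the 3 gasdermin C genes were between 4.55-fold and 8.80-fold lower. That list's median was -0.17, inside the random range, and 0.08 without the genes that also stand in another list.

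The TNF and NF-kB list and the interferon list had medians above those of random lists. Of 23 genes of the TNF and NF-kB list, 13 were higher and 1 was lower, with a median log2 fold of 0.56, above all random lists. Saa1 and several other higher members were below 1 in the control and were included only through the knockout. Apart from Saa1, the largest difference was in Ccl20, a chemokine that attracts CCR6-bearing leukocytes, at 4.08 in the control and 26.5 in the knockout. Ccl28 was 12.2 and 5.04, the 1 lower member, and Tnfaip3 was within 1.4-fold. In the interferon list, 19 of 29 genes were higher and 1 was lower, with a median of 0.74, again above all random lists. Several of the higher members were included only through the knockout, and Gbp3 only through the control. Ifit1bl1 was 12.1 and 68.0 and the ubiquitin-like modifier Isg15 was 11.7 and 47.3, while Gbp2 was 3.48 and 2.01 and Gbp3 was 1.27 and 0.86. In the antioxidant and oxidant list, 13 of 20 genes were higher and 1 was lower (Cat, which encodes catalase, at 111 and 49.2), with a median of 0.71 above all random lists. Its largest differences were in Duoxa2, the maturation factor of the epithelial dual oxidase, at 13.7 and 142, and in the glutathione transferase gene Gsta4, at 33.8 and 177. Immediate early and heat shock genes, which respond to handling as well as to injury, had medians of 0.34 (7 of 17 higher, none lower, percentile 99.1) and 0.47 (4 of 11 higher, none lower, percentile 99.8), both above the random range.

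Antigen presentation genes were lower. Of 17 genes, 12 were lower and 1 was higher, with a median log2 fold of -0.90, below all random lists. The 7 class II genes were all lower, by 2.54-fold to 4.27-fold: H2-Aa was 145 in the control and 33.1 in the knockout, H2-Ab1 was 259 and 62.6, and Cd74, the invariant chain, named after its value was seen, was 1027 and 274. Dendritic cells and B cells express class II genes too. In the macrophage and dendritic cell list, Itgax was 2.47 and 1.34 and Fcer1g was 26.3 and 13.7, but 6 of 11 genes were higher and 3 lower. Its median was 0.60, which became -0.13 at a level of at least 5. The B and plasma cell list had a median of 0.22, with 3 of 7 genes higher, none lower and 4 between. Of the 10 class I genes, 5 were lower and 1 was higher. H2-D1 was 236 and 273, and Nlrc5, the class I transactivator, was 1.27 and 2.28. Antimicrobial genes split, with 7 of 22 higher and 13 lower and a median of -0.79. Without the genes that also stand in another list, few members remained and their median was -1.36. Most of the 13 lower genes, among them Lyz1 and Defa26, also stand in the Paneth cell list. Duoxa2 and Duox2 (29.0 and 122) were higher. Reg3b, a C-type lectin secreted by enterocytes, was 9242 and 31430, and its share of the listed total was 1.38% in the control and 4.95% in the knockout. Reg3g, chosen after its value was seen, was 4890 and 14011. Reg1 (126 and 44.0) and Reg3a (187 and 46.9), of the same family, were lower.

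**Figure D2:**
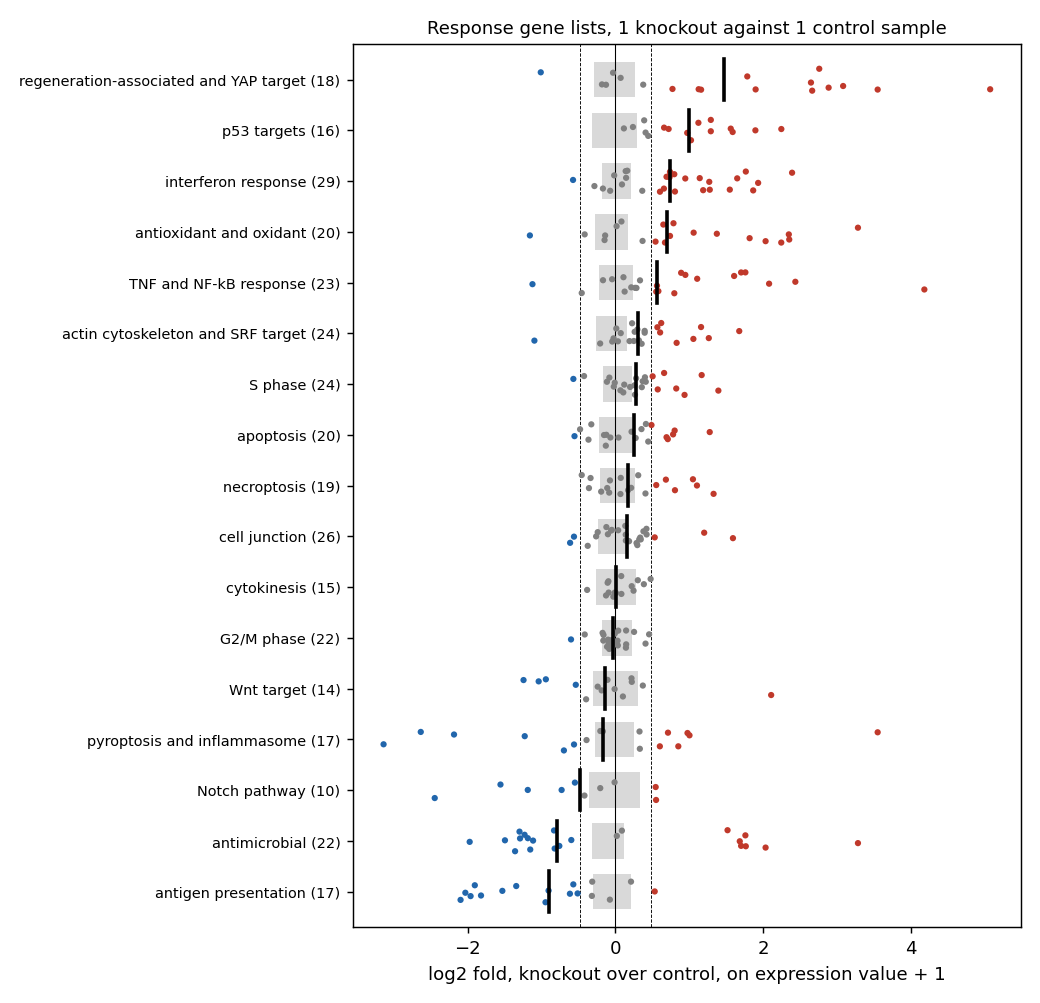
Log2 fold of knockout over control for each included member of 17 response gene lists, 1 sample per group; the number of members is in brackets, the black bar is the list median, the grey band holds the central 95% of medians of matched random lists, and dashed lines mark 1.4-fold (red higher, blue lower). The p53 target median of 1.00 and the antigen presentation median of -0.90 lie on opposite sides of their grey bands.

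The list of crypt-base stem cell markers had a lower median than random lists. Of 19 stem cell genes, 9 were lower, 2 were higher and 8 lay between, with a median log2 fold of -0.48 at percentile 0.03. Besides Olfm4, Gkn3 was 7.31 in the control and 0.88 in the knockout, Ascl2, a transcription factor of stem cell fate, was 5.80 and 1.87, and Lgr5, the R-spondin receptor that marks these cells, was 4.49 and 1.67, 2.05-fold lower (chromosome 10, 115450311 to 115587780). Cd44 (8.48 and 39.9) and Msi1 (2.80 and 5.50) were the 2 higher members. The Notch list was lower by its median, with 5 of 10 lower and 2 higher and a median of -0.48 at percentile 0.38. Lfng was 13.1 and 3.81, while the ligand genes Jag1 (2.24 and 3.72) and Dll4 (3.57 and 5.69) were higher. Among its lower members, Olfm4 also stands in the stem cell list and Atoh1, picked by the authors, in the goblet list. The Notch median is therefore not separate from those lists. Hes1, also picked by the authors, was 21.7 and 18.7, within 1.4-fold. The Wnt target list stayed inside the random range, with 4 of 14 lower, 1 higher, a median of -0.15 and a percentile of 16.4.

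Genes associated with epithelial regeneration and YAP activity were higher. Of 18 measured, 12 were higher and 1 was lower, with a median log2 fold of 1.47, above all its random lists. The median became 2.05 at a pseudocount of 0.1 and 2.66 at a level of at least 5. The filter raises it by construction, since several members, Ly6a and Il1rn among them, pass only through the knockout. Ly6a and Il1rn led this list, and Wnt5a was 1.47 in the control and 0.23 in the knockout. Areg, an EGF receptor ligand, was 4.23 and 32.2, the largest difference among the growth factor and tumour-associated genes, of which 8 of 19 were higher and 1 was lower (Mycn, 1.58 and 0.24), with a median of 0.33 at percentile 99.5.

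Most cell cycle genes lay between the 1.4-fold lines. Of 22 G2/M genes, none was higher and 1 was lower (Nusap1, 15.3 and 9.78), with a median log2 fold of -0.03, which became 0.08 under the rescaling without mitochondrial and most abundant genes. Ccnb1 was 20.2 and 28.1. Of 24 S phase genes, 7 were higher, 1 was lower and 16 lay between, with a median of 0.27 at percentile 99.2. Rrm2, a ribonucleotide reductase subunit, was 12.4 and 34.2, Ccne1, which encodes cyclin E1, was 4.44 and 11.2, and Tk1 was 34.7 and 23.1. None of the 15 cytokinesis genes passed 1.4-fold in either direction, and their median was 0.01, which became -0.002 under the median scaling. In the DNA damage response list, 1 of 18 was higher (Brca1, 1.35 and 2.74) and 2 were lower, among them H2afx at 56.9 and 26.9, with a median of 0.07 at percentile 70.4.

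Among differentiated lineages, Paneth cell genes were the lowest. Of 15, 13 were lower and none was higher, with a median log2 fold of -1.02, below all random lists. Lyz1, the Paneth cell lysozyme, was 2797 in the control and 1653 in the knockout, Defa26 was 239 and 96.7, and Pnliprp2 was 54.8 and 13.2. The 7 defensin genes were each lower, by 1.77-fold to 2.46-fold. Mmp7, which processes defensins, was 146 and 179. In the goblet list, 8 of 18 were lower and 1 was higher, with a median of -0.45 at percentile 0.02. Fcgbp was 1132 and 542, whereas Muc2, the main secreted mucin, was 38.6 and 44.9. In the tuft list, 7 of 11 were lower and none was higher, with a median of -0.64 at percentile 0.12, and Dclk1 was 4.26 and 0.30. Enteroendocrine genes went both ways (8 of 18 higher, 3 lower, median 0.16, percentile 88.9): Chga was 24.9 and 38.9, Tac1 was 3.34 and 13.8, and the neurotensin gene Nts was 25.6 and 9.01.

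Absorptive enterocyte genes were mixed, with 3 of 23 higher and 6 lower and a median log2 fold of -0.20 at percentile 27.7. The brush border enzyme gene Alpi was 270 in the control and 295 in the knockout. The fatty acid binding protein gene Fabp1 was 3018 and 6049 and the retinol binding protein gene Rbp2 was 2862 and 5321, while lactase, Lct, was 279 and 81.0 and Apoc3 was 503 and 153. The villus tip list was higher by its median (6 of 14 higher, none lower, median 0.41, percentile 99.96), led by Fos at 21.6 and 43.6 and Enpp3 at 25.7 and 49.6. Fos and 1 other of the 6 higher members also stand in the immediate early list, and without genes shared between lists the villus tip median was 0.46. Villus bottom genes split into 4 higher and 5 lower of 10, with a median of -0.49 at percentile 0.30, below the random range. Regional markers differed as well. Of 10 proximal genes, 7 were lower and 1 was higher, with a median of -0.68, below all random lists. Slc40a1, the iron exporter, was 4.14 and 0.44. Of 10 distal genes, 4 were higher and 4 lower, with a median of 0.24 at percentile 96.2. The ileal bile acid binding protein gene Fabp6 was 125 and 741, 5.89-fold higher, and the mucin gene Muc3 was 61.0 and 324, whereas Cubn was 25.7 and 4.05.

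Markers of other cell types that the preparation could hold also differed. T cell and intraepithelial lymphocyte genes were lower in 16 of 21 cases and higher in 1, with a median log2 fold of -0.70, below all random lists. Ccl5 was 540 in the control and 228 in the knockout, and Gzma, which encodes granzyme A, had a log2 fold of -1.11. Of the plasma cell genes, 3 were higher: Igha was 50.4 and 221, Jchain was 9.88 and 32.6, and Igkc, named after its value was seen, was 167 and 494. The other 4 of the 7 measured B and plasma cell genes lay within 1.4-fold, and the list median was 0.22. At a level of at least 5 only the 3 higher genes remained, with a median of 1.63. Of 11 macrophage and dendritic cell genes, 6 were higher and 3 lower, with a median of 0.60 that became -0.13 when only genes with a level of at least 5 were used. Cd68 was 0.27 and 3.02, and Fcer1g was 26.3 and 13.7. The 4 measured neutrophil genes were all higher, at low levels, with Ltf at 2.58 and 9.66 and a median of 1.21 that became 2.78 at a pseudocount of 0.1. All but Ltf were below 1 in the control and were included only through the knockout, so the filter fixed their direction. Fibroblast genes (4 of 13 higher, 1 lower) had a median of 0.37, which became -0.25 at a level of at least 5. Endothelial, smooth muscle and erythroid lists had 4, 5 and 3 measured genes, with medians of 0.62, 0.57 and 0.98. Of the gastric list 1 gene was measured and of the enteric glia and neuron list none.

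**Figure D3:**
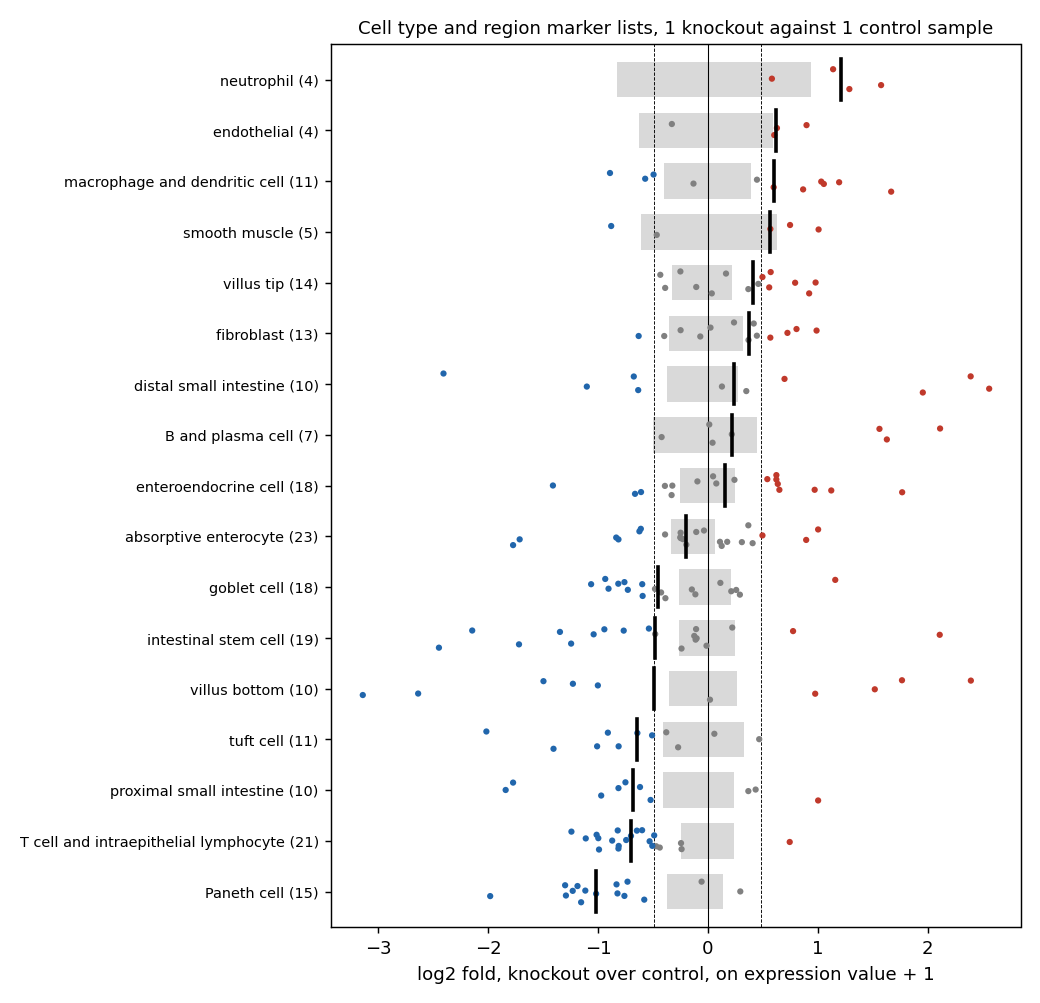
Log2 fold of knockout over control for each included member of 17 cell type and region lists, 1 sample per group; the number of members is in brackets, the black bar is the list median, the grey band holds the central 95% of medians of matched random lists, and dashed lines mark 1.4-fold (red higher, blue lower). The Paneth cell median of -1.02 and the T cell median of -0.70 lie below their grey bands.

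Genes of the structures that non-muscle myosin II acts on were higher in some cases and between the 1.4-fold lines in most. Of 26 junction genes, 3 were higher, 2 were lower and 21 lay between, with a median log2 fold of 0.15 at percentile 96.9. Cldn2, a pore-forming claudin, was 26.8 in the control and 82.7 in the knockout, and Cldn4 was 12.9 and 30.9, while Cldn15 was 299 and 195. In the actin and SRF target list, 8 of 24 were higher and 1 was lower, with a median of 0.31 at percentile 99.97. Pdlim7 was 3.83 and 14.4 and Cnn3 was 40.9 and 18.6. In the integrin and matrix list, 6 of 17 were higher and 1 was lower, with a median of 0.32 at percentile 99.4. Itga1 was 4.79 in the control and 2.14 in the knockout, the 1 lower member.

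The authors' deposited table also carried their own selection of 28 genes, 12 of them with notes such as a pathway name. In it, 9 genes were at least 1.4-fold higher, 8 were at least 1.4-fold lower and 11 lay between. In the authors' deposited table the folds were 5.41 for Ccl20, 4.31 for Cd44, 2.42 for Bax, 2.18 for the p53 regulator Mdm2, 1.65 for the cell cycle inhibitor Cdkn1a, 0.49 for Lgr5 and 0.42 for Ascl2. Mki67, Hes1, Axin2 and Bmi1 had folds of 0.89, 0.87, 0.85 and 0.84 in the authors' deposited table. How these genes were chosen is not given in the sources used here; as far as they were chosen on these samples, their directions are not independent evidence.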

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

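The left-out rows with recurring or converted names, the lists without shared genes, and 2 of the rescalings of the named genes were chosen after seeing the data; the other alternatives were set before. The Myh9 level stayed lower in the knockout under the 4 alternatives tried for it, with log2 folds between -2.86 and -2.68. The count of lower genes was 1284 where a level of at least 5 was required, with 8566 genes left, and at a 2-fold threshold 546 genes were higher and 520 lower. Every other alternative kept both counts within 1.5 times the main ones. The number of lists outside the random range was 37 of 54 as reported and between 30 and 37 under the alternatives. At a level of at least 5 the macrophage and dendritic cell median became -0.13 and the fibroblast median -0.25, with fewer genes in each list. Of 371 list medians recomputed, 8 moved by over 1.4-fold, changed sign in a list outside the random range, or changed sign with a log2 shift over 0.3, these 2 included; the others were regeneration (2.05 at a pseudocount of 0.1, 2.66 at a level of at least 5), neutrophil (2.78), B and plasma cell (1.63), circadian clock (-0.37) and antimicrobial (-1.36) genes. Where the filter at 5 or the removal of shared genes was used, fewer members remained. The filter takes the larger level, so members could pass it through the knockout alone. Another 4 medians, of lists inside the random range, changed sign by less: G2/M (0.08), cytokinesis (-0.002), pyroptosis (0.08) and bile acid, iron and vitamin transport (0.016). Of 824 recomputed folds of named genes, 69 crossed the 1.4-fold line or moved by over 1.4-fold, most of them low-level genes under a pseudocount of 0.1. The 24 genes with the largest differences kept their direction and their side of the 1.4-fold line under a pseudocount of 0.1 and under the median scaling. That outcome was fixed in advance. A smaller pseudocount enlarges such folds, and the median scaling multiplied the knockout by only 0.994. Rescaling without the most abundant genes shifts log2 folds of well-expressed genes by 0.11, against 0.49 for the 1.4-fold line. No paired analysis was possible because each group has 1 sample. Depth is unknown, and no library could be left out.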

Other observations

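Metabolic genes differed in opposite directions between pathways. Cholesterol synthesis genes were higher in the knockout (13 of 22 higher, 1 lower, median log2 fold 0.59, above all random lists), with the demethylase Cyp51 at 21.7 in the control and 56.8 in the knockout. Fatty acid oxidation and PPAR target genes had a lower median (11 of 22 lower, 4 higher, median -0.46, percentile 0.03), with the coactivator Ppargc1a at 15.3 and 5.21, though Pdk4 was 1.27 and 3.50. Xenobiotic metabolism genes had a lower median (12 of 27 lower, 4 higher, 11 between, median -0.40, percentile 0.02): Ugt1a1 was 182 and 62.7 and Cyp2c55 was 22.2 and 7.34, while the glutathione transferases Gsta2 (10.1 and 56.8) and Gsta3 (3.24 and 29.8) were higher. Mitochondrial-genome transcripts were lower (9 of 14, none higher, median -0.60), and they made up 9.11% of the listed total in the control and 6.78% in the knockout. Of the 28 genes of that list 14 had a row, so these shares do not measure mitochondrial content. Nuclear respiratory chain genes (7 of 28 lower, none higher, median -0.36, percentile 0.65) and cytosolic ribosomal protein genes (10 of 79 lower, 3 higher, median -0.29, percentile 0.11) had medians below 0 by less. Unfolded protein and integrated stress response genes had a higher median (8 of 21, none lower, median 0.30, percentile 99.6), with Asns at 24.9 and 44.3. The bile acid, iron and vitamin transport list split into 5 higher and 6 lower of 13 (median -0.12, and 0.016 with no filter).

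Immunoglobulin V segments were higher in 79 of 111 cases and lower in 16, with a median log2 fold of 1.20. Among clock genes, 4 of 15 were higher and 5 lower (median 0.04, and -0.37 at a level of at least 5): the output gene Dbp was 5.73 in the control and 1.20 in the knockout, Usp2 was 34.6 and 14.5, and Cry1 had a log2 fold of 1.03. Xist, transcribed from the inactive X chromosome of females, was 11.1 and 15.9, and 2 of the 6 measured sex-linked genes were higher and none lower (median 0.39). All 6 are X-linked, and Xist was present in both samples, so these values give no sign that the 2 animals differed in sex. Few exocrine pancreas (5), colon (4) and mast cell (3) genes were measured, with medians of -0.99, -0.34 and -0.37.

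For the 3 patterns below, the tests of crypt cells, of the p53 targets alone and of lymphocytes were chosen after the results they bear on had been seen; the others were set after single genes, but before any list median, had been seen. Intervals are 95% bootstrap intervals over genes, and genes are not replicates.

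The stem cell list had a median log2 fold of -0.48 in the knockout. A smaller share of crypt cells in the knockout preparation would lower cycling genes too. The pooled S phase and G2/M genes had a median 0.57 above that of the stem cell list (0.13 to 1.17). That does not decide against fewer crypt cells, because the S phase list was itself above the random range. Unlike gene sets also need not move by the same amount. The 3 rescalings shifted log2 folds by at most 0.11, so the median stayed at -0.37 or lower. A scaling difference of the kinds they estimate is therefore too small to give the pattern. A loss of the crypt base alone, where Paneth cells also sit, is not excluded by these tests, whether from the genotype or from the dissociation. With 1 animal per genotype, an effect of Myh9 loss and a difference between animals remain open.

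The p53 and NF-kB lists had medians above those of random lists, and pooled with the necroptosis list, which was inside the random range, they had a median log2 fold of 0.56. Stress during tissue handling cannot be told apart for the 3 lists together, because the immediate early and heat shock genes differed from them by only -0.15 (-0.54 to 0.23). For 15 p53 targets alone the difference was -0.61 (-1.07 to -0.03). That does not decide against handling, because handling need not move unlike gene sets by the same amount. The immediate early and heat shock lists were also above the random range themselves. More T cells and intraepithelial lymphocytes are argued against by their own median of -0.70 (-0.82 to -0.51), while pooled leukocyte markers gave -0.42 (-0.53 to 0.22) and leave plasma cells and myeloid cells open. A response of the epithelium to Myh9 loss is a hypothesis that remains among the open explanations.

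Enterocyte genes differed in both directions, with Lct lower and Fabp1 higher. If the 2 preparations held different stretches of the small intestine, proximal and distal markers would part. The proximal median was below all its random lists, while the distal median was inside the random range. These medians differed by -0.92, but the interval of -2.74 to 0.56 is too wide to decide. Sampling of different stretches therefore cannot be told apart from a change within enterocytes. Members of both lists went both ways: Fabp1 was higher and Lct lower in the proximal list, so the genes of the pattern are part of the test, and Fabp6 and Muc3 were higher and Cubn lower in the distal list.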
